A study of Mus musculus with 6 samples.

How the data were processed

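RNA was measured by sequencing in 6 libraries from activated group 2 innate lymphoid cells (ILC2s) of mouse lung, 3 from mice labelled C57BL/6 (wild type, WT) and 3 labelled Cnr2 KO. Per the labels' protocols, mice received 0.5 µg of recombinant mouse IL-33 into the nose on 3 days, cells were isolated on day 4, and, per the design text, sorted ILC2s were cultured for 18 h. Per the labels' protocols, cDNA was made from 10 pg of RNA with a low-input kit (SMARTer Ultra Low Input v3). The series title names adipose tissue, whereas every sample label and the design text name lung, and lung was used here.

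The deposited table holds expected counts per gene and library, estimated counts that need not be whole: 59.08 to 81.23% of the values lay within 0.02 of a whole number. Per the submitters' processing notes, Partek 10.0, STAR 2.7.8, DESeq2 and the genome build mm10 were used, with no role or order stated. The counting method and its strand setting are not given in the sources used here, so reads of overlapping genes cannot be assigned between them. The table has 16588 genes, with 0 blank and 0 repeated names and a lowest total of 10 counts over the 6 libraries. Of these, 16230 matched GENCODE mouse release M21 (GRCm38, the build named mm10), 16138 with the same start, and positions printed are from that annotation.

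Values were rounded to whole counts. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and genotype as the only term, which tested 12150 genes and left out 4438. Benjamini-Hochberg adjusted p-values under 0.05 were called changed, and all adjusted p-values of single genes are from this test unless another tool is named. A level is a TMM-scaled CPM value, as mean ± SD over 3 libraries. A log2 fold change is given with an approximate standard error (SE), its absolute value divided by the square root of the test's F statistic. On counts simulated for this comparison over 12134 genes, the test recovered 48%, 82%, 94% and 98% of the 50 genes each changed 1.25, 1.5, 2 and 4-fold, and 6.94% of its calls were unchanged genes. The changed genes were drawn from the better-counted genes, and 11934 genes were left unchanged, whereas 66.3% of the tested genes were called in the data. These rates therefore do not cover low-count genes or so large a share of changed genes.

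A total of 33 gene lists was fixed before the data were examined, and camera (limma 3.58.1, preset correlation 0.01, two-sided) tested the 25 lists with at least 5 tested genes, with Benjamini-Hochberg adjustment over lists. Overlap of each list with the called genes was tested with Fisher's exact test over 50 combinations of list and direction, with the tested genes as background. The rule for named genes was also fixed then: Cnr2; the 10 genes per direction with the largest log2 fold change among called genes of at least 5 CPM with no overlap between groups, leaving out predicted, pseudogene and ribosomal protein symbols; a fixed set of genes of ILC2 biology; and the members of each list with the smallest p, up to 4 for a list that passed and up to 2 for any other. Summed marker levels and library measures, 18 in all, were compared by a two-sided exact permutation test, which cannot go below 0.1 with 3 against 3. Called genes within 10 Mb of Cnr2 were compared with other tested genes by Fisher's exact test, two-sided.

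Alternatives were DESeq2 size factors, no filter and a stricter filter, a block for replicate number, leaving out each library, DESeq2 1.42.0, limma-voom with quality weights, other thresholds, an estimated correlation, fry, and other windows around Cnr2. Alternatives chosen after seeing the data were thinning of WT replicate 2 to the mean depth of the other 5 libraries and an offset for GC content and length. Pairs of libraries of the same group differed by more than sampling noise (chi-square per gene 4.11 to 9.02), so each counted as 1 replicate. The labels do not say that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. A bound against a group with 0 counts takes a floor of 3 counts over that group, and is the lower of the ratio of pooled counts and the ratio of the mean level to that floor. Intervals and floors cover counting error only.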

Results

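The data comprise gene counts from 6 RNA-seq libraries of lung ILC2s, tissue-resident lymphocytes that respond to IL-33 with type 2 cytokines, taken from mice given IL-33 and cultured for 18 h. There were 3 WT libraries and 3 libraries labelled Cnr2 KO. Cnr2 encodes the cannabinoid receptor CB2, and the comparison asked how ILC2s of the 2 genotypes differ. Total counts were 19056174, 129617689 and 19091963 in WT replicates 1, 2 and 3 and 19399819, 18811836 and 17867541 in the libraries labelled Cnr2 KO. WT replicate 2 was 6.88 times as deep as the mean of the other 5 libraries. Log2 CPM values correlated at 0.9965 to 0.9977 between libraries of the same group and at 0.9732 to 0.9759 between groups.

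Cnr2 transcripts were counted in all 6 libraries and were higher in the libraries labelled Cnr2 KO, against the direction of the label. Cnr2 (ENSMUSG00000062585.11, chromosome 4, 135895394 to 135920207, GRCm38) had 76, 503 and 60 counts in WT replicates 1, 2 and 3 and 147, 139 and 135 counts in the libraries labelled Cnr2 KO. Its level was 3.69 ± 0.449 CPM in WT and 7.49 ± 0.0627 CPM in the libraries labelled Cnr2 KO (SD, n = 3 each). This was a 2.01-fold difference, with a log2 fold change of 1.01 (SE 0.16, edgeR adjusted p = 2.11e-05). The annotation places 0 other genes over Cnr2. The table has 1 value per gene and library, so a deleted exon could not be looked for, and the group names below are those of the labels.

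Most of the listed ILC2 genes, such as Gata3, interferon-induced genes and mitotic genes were higher in the libraries labelled Cnr2 KO. By contrast, most of the listed NF-kB response genes, cytokines and glycolytic genes were lower in those libraries. Of 12150 genes tested, 4019 were higher and 4034 were lower in the libraries labelled Cnr2 KO, 66.3% of those tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes were found in 1080 genes that were higher and 908 that were lower, and at least 4-fold changes in 314 and 250. The 3 values of each group did not overlap in 68.9% of the genes, where chance gives 10%. The spread between libraries of a group was small, with a common biological coefficient of variation of 0.0615. The ribosomal protein share of counts was 2.22 ± 0.0727% in WT and 1.51 ± 0.1% in the libraries labelled Cnr2 KO (n = 3 each, exact permutation p = 0.1, the smallest possible), and the mitochondrial share was 0.449 ± 0.0398% and 0.449 ± 0.113%.

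Among the genes with the largest changes, Pcsk1, a prohormone-processing protease, stood at 30.1 ± 4.15 CPM in WT and 701 ± 45.4 CPM in the libraries labelled Cnr2 KO, a log2 fold change of 4.53 (SE 0.08). P2ry1, an ADP receptor, was 33.2-fold higher, Serpinb1a, a protease inhibitor, 31.8-fold, and Anxa1, which encodes annexin A1, 21.8-fold. Ccl21b had 0, 10 and 0 counts in the WT libraries and 225, 178 and 169 in those labelled Cnr2 KO. Mndal, Ifi209, Isg20, Npas2 and Gbp6 completed the 10 genes, at 18.5 to 55.6-fold higher. In the other direction Ccr7, the receptor that guides cells to lymph nodes, was at 466.5 ± 18.1 CPM in WT and 7.73 ± 0.891 CPM in the libraries labelled Cnr2 KO, 60.3-fold lower. Satb1, a chromatin organiser, was 40.9-fold lower, Mycl, a MYC family member, 103.7-fold, Il1rn, which encodes the IL-1 receptor antagonist, 124.0-fold, and Il9 122.0-fold. Enpp2, Cd300a, Plek and Flvcr2 were 47.8 to 158.6-fold lower. Shisa3 had 2 counts in the 3 libraries labelled Cnr2 KO and 2168 in WT, a ratio of 362.3 with a 95% counting interval of 100.2 to 2994. Without WT replicate 2, P2ry1 was 21.5-fold and Mndal 27.5-fold higher. Without replicate 3 of those labelled Cnr2 KO, Il9 was 699.8-fold lower, and Il1rn, with 2 counts left in that group, had a ratio of pooled counts of 273.8 (95% counting interval 75.7 to 2262). Without replicate 1 of those labelled Cnr2 KO, Enpp2 was 309.4-fold lower, and Cd300a, also with 2 counts left, had a ratio of 228.9 (63.3 to 1891). Adjusted p-values of these 20 genes in edgeR were 2.63e-12 or lower. Ccl21b and the Ifi and Gbp genes have close relatives, and Mndal, P2ry1, Anxa1, Ifi209, Npas2, Gbp6, Shisa3, Enpp2, Plek and Satb1 overlap 1 to 6 other annotated genes, so their counts are uncertain to that extent, as are those of other named genes with overlapping neighbours, among them Gata3 and Stab2.

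**Figure D1:**
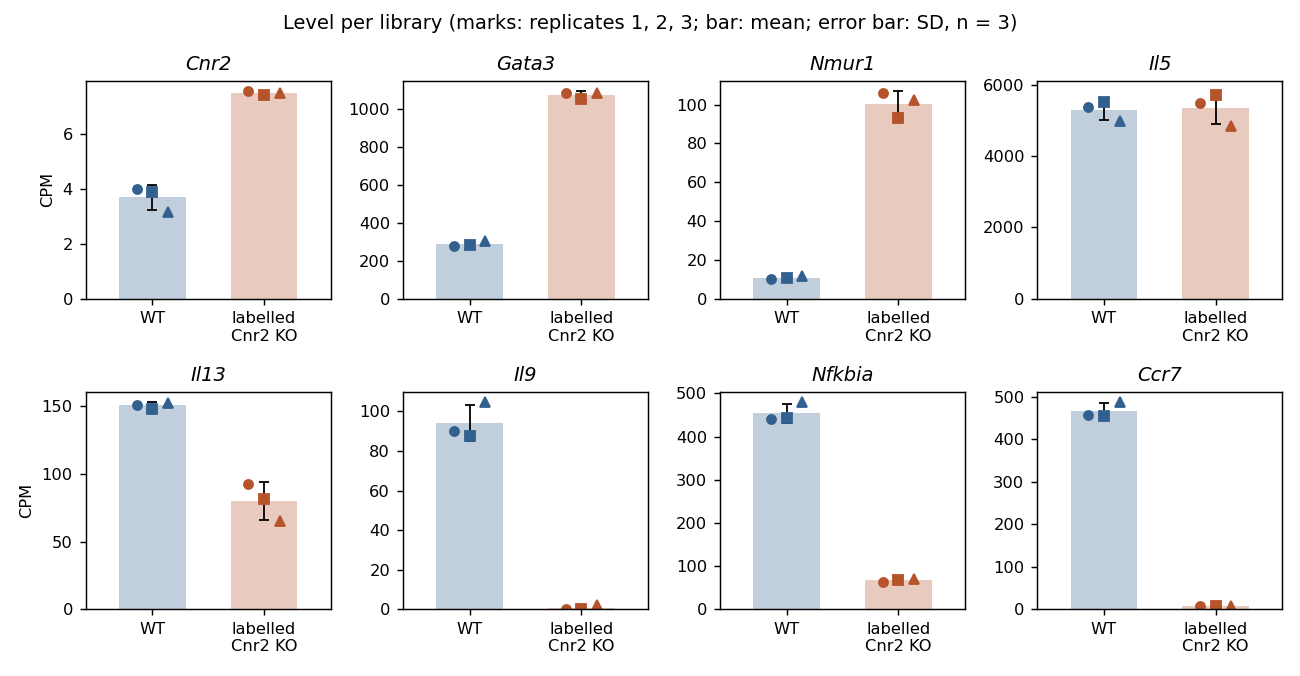
Level (TMM-scaled CPM, vertical axes from 0) of 8 genes in the 3 WT libraries and the 3 libraries labelled Cnr2 KO; marks are replicates 1, 2 and 3, bars are means and error bars are SD (n = 3). Il5 was at 5285 and 5354 CPM in the groups and passed the test only with the GC and length offset, while Gata3 was 3.72-fold higher and Nfkbia 6.78-fold lower in the libraries labelled Cnr2 KO.

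Genes of ILC2 identity were mostly higher in the libraries labelled Cnr2 KO. Gata3 (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034), the transcription factor that specifies type 2 lymphocytes, was at 288 ± 13.5 CPM in WT and 1073 ± 18.7 CPM in the libraries labelled Cnr2 KO. Nmur1, the neuromedin U receptor, was 9.39-fold higher, Il9r 4.28-fold, Stab2 12.3-fold and Arg1 2.31-fold. Rora was 2.24-fold, Icos 2.02-fold, Il1rl1, the IL-33 receptor chain, 1.71-fold, Klrg1 1.65-fold and Il7r 1.32-fold higher. Id2 was 1.11-fold higher (edgeR adjusted p = 7.78e-03, and 0.0566 without replicate 2 of those labelled Cnr2 KO). Il2ra, the high-affinity IL-2 receptor chain, went the other way, from 5450.5 ± 125.8 to 2680.1 ± 177.6 CPM. Of 28 list members tested, 22 were higher and 5 lower, the same counts as when adjusted over the list alone. The list's median log2 fold change was 0.79 (camera adjusted p = 9.48e-11, and adjusted p = 0.0379 with an estimated correlation).

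Among cytokines, Il13 and Areg were lower and Csf2 was higher in the libraries labelled Cnr2 KO, whereas the call of Il5 changed with the correction for GC content and length. Il5 was at 5285 ± 273.8 CPM in WT and 5354 ± 461 CPM in the libraries labelled Cnr2 KO (log2 fold change 0.02, SE 0.05, edgeR adjusted p = 0.771), but passed as higher with the GC and length offset (log2 fold change 0.18, adjusted p = 9.50e-03, against 0.101 to 0.997 in the other alternatives). Il4 was at 7.61 ± 1.17 and 8.53 ± 0.847 CPM (adjusted p = 0.365). Il13 was 1.88-fold lower (150.5 ± 2.47 against 79.8 ± 13.9 CPM), Areg, which encodes the epithelial growth factor amphiregulin, 1.74-fold lower, and Csf2, which encodes GM-CSF, 3.31-fold higher. Il6 was 7.67-fold, Il10 9.94-fold, Lif 11.4-fold and Penk 5.72-fold lower. Of 25 members tested, 5 were higher and 16 lower, the same counts as when adjusted over the list alone. The median log2 fold change was -0.76 (camera adjusted p = 3.54e-06), and the call was lost, at adjusted p = 0.204 with an estimated correlation. Il22 had 0 counts in the libraries labelled Cnr2 KO, so it was at least 26.2-fold lower against a floor of 3 counts over the group.

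Most genes of the NF-kB response list, which also holds components of the pathway, were lower in the libraries labelled Cnr2 KO, whereas Nfkb1 was higher. Nfkbia, which encodes the inhibitor of NF-kB, was at 454.6 ± 22 CPM in WT and 67.0 ± 3.05 CPM in the libraries labelled Cnr2 KO, 6.78-fold lower. Tnfaip3, the feedback inhibitor A20, was 6.49-fold, Nfkb2 3.64-fold and Traf1 3.38-fold lower, while Nfkb1 was 3.38-fold higher. Of 27 members tested, 3 were higher, 20 lower and 4 did not pass the test, with 3 higher and 21 lower when adjusted over the list alone. The median log2 fold change was -1.12 (camera adjusted p = 2.91e-14, and adjusted p = 0.0645 with an estimated correlation). Immediate early genes moved apart: Junb was 4.94-fold lower and Dusp6, a phosphatase acting on ERK, 6.51-fold higher, and of 33 members 7 were higher and 17 lower (camera adjusted p = 0.384).

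Most interferon-induced genes were higher in the libraries labelled Cnr2 KO. Gbp4, a guanylate-binding protein, was at 41.2 ± 3.3 CPM in WT and 181.5 ± 6.06 CPM in the libraries labelled Cnr2 KO, and Ddx58, the RNA sensor RIG-I, was 6.09-fold higher. Zbp1, a nucleic acid sensor, was 5.02-fold and Gbp7 4.96-fold higher, whereas Bst2 was 1.38-fold lower. Of 26 members tested, 21 were higher and 3 lower, the same counts as when adjusted over the list alone. The median log2 fold change was 1.42 (camera adjusted p = 2.16e-06, and adjusted p = 0.107 with an estimated correlation).

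Most glycolytic genes were lower in the libraries labelled Cnr2 KO. Hk2, which encodes hexokinase 2, was 3.21-fold lower, the lactate transporters Slc16a1 and Slc16a3 were 2.67-fold and 2.64-fold lower, and Pfkl, a phosphofructokinase subunit, was 2.03-fold lower. Of 26 members, 4 were higher and 19 lower, the same counts as when adjusted over the list alone. The median log2 fold change was -0.49 (camera adjusted p = 1.49e-05, and adjusted p = 0.204 with an estimated correlation). Other metabolic lists did not pass camera, although single members changed. Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, was 1.91-fold higher, and Dgat1 and Fabp5 were 2.34-fold and 2.31-fold lower. Of the fatty acid list 14 of 32 members were higher and 8 lower, with a median of 0.05 and a mean of 0.05 against a camera direction of down (adjusted p = 0.799). Cd36, a fatty acid transporter, was near the count floor, at 0.265 ± 0.263 CPM in WT and 0.999 ± 0.914 CPM in the libraries labelled Cnr2 KO (edgeR adjusted p = 0.0181), and its groups overlapped. Its adjusted p was 0.0724 without WT replicate 2, 0.0617 without WT replicate 3, 0.376 without replicate 3 of those labelled Cnr2 KO and 0.128 in DESeq2 with the replicate block. Of the cholesterol and fatty acid synthesis list 5 of 35 members were higher and 17 lower (adjusted p = 0.23), with Idi1 2.36-fold and Scd2 1.69-fold lower. Of the oxidative phosphorylation list 4 of 44 were higher and 21 lower (adjusted p = 0.175), with Cyc1 1.61-fold and Uqcrc1 1.34-fold lower, and of the TCA cycle list 4 of 22 were higher and 10 lower (adjusted p = 0.239), with Idh3a 1.61-fold and Suclg2 1.74-fold lower. Nqo1, an antioxidant enzyme, was 5.0-fold higher and Gstm1 5.31-fold lower in an oxidative stress list with 15 of 27 higher and 6 lower (adjusted p = 0.23). In the unfolded protein response list 12 of 30 members were higher and 9 lower (adjusted p = 0.477), with Xbp1 1.82-fold and Pdia3 1.75-fold higher.

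Most mitotic genes were higher in the libraries labelled Cnr2 KO. Cdc25b, a phosphatase that starts mitosis, was 2.34-fold higher, Mki67 1.83-fold, Kif11 1.63-fold and Ccnb2 1.58-fold. Of 38 G2/M members, 28 were higher and 4 lower, the same counts as when adjusted over the list alone. The median log2 fold change was 0.31 (camera adjusted p = 1.49e-03, and adjusted p = 0.276 with an estimated correlation). Of 37 G1/S genes 18 were higher and 7 lower (adjusted p = 0.324), with Ccnd3 1.37-fold and Pola1 1.4-fold higher. In the survival list 10 of 31 were higher and 15 lower (adjusted p = 0.376), with Pim2 3.05-fold and Trp53 2.18-fold lower and Bcl2 1.21-fold higher, and in the autophagy list 16 of 29 were higher and 4 lower (adjusted p = 0.23), with Tfeb 2.83-fold and Gabarap 1.54-fold higher.

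Receptors for migration changed in both directions. S1pr1, which directs exit from tissue, was 14.0-fold lower and Ccr4 4.11-fold lower in the libraries labelled Cnr2 KO, while Itgb7, a gut-homing integrin chain, was 3.61-fold higher. Of 27 members, 18 were higher and 8 lower, the same counts as when adjusted over the list alone. The median log2 fold change was 0.80 and the mean 0.23 (camera adjusted p = 0.0397, and adjusted p = 0.204 with an estimated correlation). Without WT replicate 1, 2 or 3 the adjusted p was 0.0710, 0.0722 and 0.0609. Cd200r1, an inhibitory receptor, was 4.25-fold and Tnfsf14 10.1-fold higher in a receptor list with 11 of 24 higher and 8 lower (adjusted p = 0.164), and in the cytokine signalling list, with 15 of 32 higher and 12 lower (adjusted p = 0.29), Stat4 was 5.29-fold higher and Stat5a 1.97-fold lower. In the endocannabinoid list 6 of 16 were higher and 5 lower (adjusted p = 0.721), and 2 were at least 2-fold higher and 3 at least 2-fold lower. Trpv2 was 1.91-fold higher and Fabp5 2.31-fold lower. The list's median was 0.05 and its mean -0.17, against a camera direction of up. Adjusted over the list alone, counts differed from those over all genes in 5 of the 33 lists and were the same in 28.

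**Figure D2:**
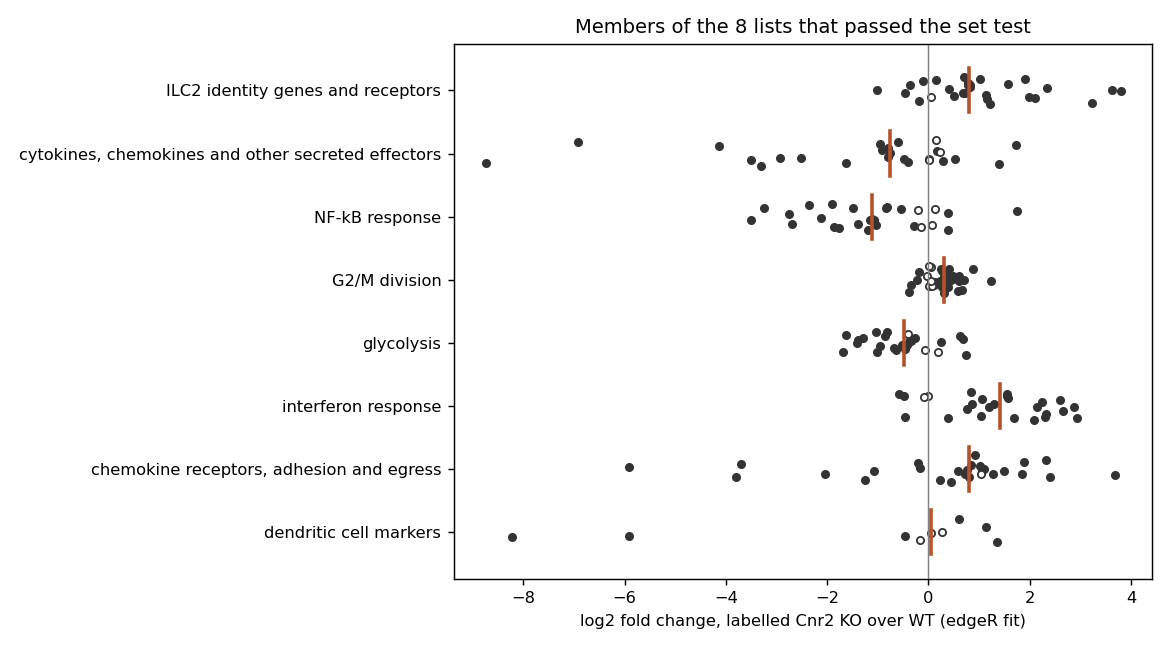
Log2 fold change (edgeR fit, libraries labelled Cnr2 KO over WT, horizontal axis) of each tested member of the 8 lists that passed camera; filled points passed the adjusted p threshold, open points did not, and the vertical bars are medians. NF-kB members have a median of -1.12 and interferon members a median of 1.42. The values of Il22 and Batf3, at 0 counts in the libraries labelled Cnr2 KO, are fitted values that depend on the prior count.

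Markers of other cell types also differed between the groups, in some lists mostly through a single gene and in others, such as the T cell and ILC3 lists, through several. T cell markers summed to 163.5 ± 3.94 CPM in WT and 241.6 ± 8.12 CPM in the libraries labelled Cnr2 KO, B cell markers to 20.9 ± 0.674 and 54.1 ± 1.57 CPM, and ILC3 markers to 55.7 ± 0.699 and 120.8 ± 8.03 CPM (n = 3 each, exact permutation p = 0.1 for each, the smallest possible, and 0.15 after Benjamini-Hochberg adjustment over 18 measures). Macrophage markers summed to 446.3 ± 10.3 and 891.2 ± 41.5 CPM, mostly Ctsd, a lysosomal protease found in many cell types, and dendritic markers to 591.3 ± 17.3 and 135.9 ± 2.85 CPM, mostly Ccr7. Endothelial markers summed to 125.5 ± 3.71 and 49.0 ± 0.982 CPM, mostly Pecam1, which was 2.75-fold lower. Epithelial (22.3 ± 8.42 and 51.7 ± 4.36 CPM, mostly Epcam), eosinophil, basophil and mast cell (20.1 ± 1.93 and 42.4 ± 1.5 CPM) and erythroid markers (1.27 ± 0.383 and 6.32 ± 1.02 CPM) were higher in every library labelled Cnr2 KO than in every WT library (exact permutation p = 0.1 each). Neutrophil (6.31 ± 6.7 and 1.57 ± 1.37 CPM), NK cell (93.9 ± 13.3 and 89.5 ± 6.82 CPM) and fibroblast markers (18.6 ± 7.86 and 21.2 ± 8.34 CPM) overlapped between groups. The dendritic list passed camera as lower with 3 of 9 members higher and 3 lower (adjusted p = 0.0278, and adjusted p = 0.258 with an estimated correlation), although its median log2 fold change was 0.06 and its mean -1.26, or -0.81 with Batf3 at its bound. Ccr7 and Batf3 carried that direction: Batf3 had 163 counts in WT and 0 in the libraries labelled Cnr2 KO, at least 18.2-fold lower against a floor of 3 counts over the group, while Xcr1 was 2.21-fold higher. T cell (8 of 12 higher, 3 lower, adjusted p = 0.2, and 0.0469 with the stricter filter), ILC3 (3 of 8 higher, 2 lower, median 0.35, mean -1.45, or -0.41 with Il17f and Il22, both at 0 counts in the libraries labelled Cnr2 KO, at their bounds, camera direction up, adjusted p = 0.23), eosinophil, basophil and mast cell (5 of 8 higher, 1 lower, adjusted p = 0.23) and fibroblast lists (1 of 12 higher, 0 lower, adjusted p = 0.799) did not pass. The remaining 8 lists had fewer than 5 tested genes: B cell 2 of 2 higher, NK cell 1 higher and 1 lower of 4, macrophage 2 of 4 higher, epithelial 1 higher and 1 lower of 3, endothelial 3 of 3 lower, erythroid 1 of 1 higher, neutrophil 0 tested and sex-linked genes 3 of 4 higher, with the Y-linked Ddx3y at 47.8 ± 1.71 and 56.2 ± 3.07 CPM.

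By overlap with called genes, 7 of the 50 combinations of list and direction were enriched (Fisher's exact test, adjusted p under 0.05). Higher genes were enriched for ILC2 identity (odds ratio 7.45), interferon response (8.54), G2/M division (5.70) and chemokine receptors and adhesion (4.06), and lower genes for NF-kB response (5.77), glycolysis (5.48) and cytokines (3.59). This test treats genes as independent, and of these lists ILC2 identity alone passed camera with an estimated correlation (adjusted p = 0.0379), against adjusted p = 0.0645 for NF-kB response, 0.107 for interferon response, 0.276 for G2/M division and 0.204 for each of the other 3. The estimate was below the preset 0.01 for ILC2 identity (-0.0155) and for chemokine receptors and adhesion (-0.00171). A higher correlation is therefore not why the camera p-values of these 2 lists rose. For the other enriched lists the estimate was above the preset, from 0.0324 (interferon response) to 0.109 (cytokines), so correlation may be part of the rise there. Another 2 were depleted, G2/M genes among lower genes (odds ratio 0.236) and oxidative phosphorylation genes among higher genes (0.202). In 9 other splits of the 6 libraries, 3 to 10 lists passed camera, against 8 in the labelled split. Those splits mix both labels unevenly and keep part of the difference between them, so no conclusion is drawn from this.

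Whether genes within 10 Mb of Cnr2 were called more often than other genes depended on the fit. In that window on chromosome 4, 141 of 200 tested genes (70.5%) were called, against 66.4% of the others (Fisher's exact test, odds ratio 1.21, 95% interval 0.883 to 1.67, p = 0.257). Id3 and E2f2 lie close to Cnr2, which ends at 135920207: Id3 starts at 136143497 and E2f2 ends at 136196057. They were 4.96-fold and 2.44-fold higher, a pair chosen after their values were seen. Within 2 Mb of Cnr2, 7 of 50 tested genes (14%) were called with at least a 2-fold change, against 16.2% of the others. Over all called genes the odds ratio within 20 Mb was 1.30 (Fisher's exact test, p = 0.0203), and within 10 Mb without WT replicate 2 it was 1.36 (p = 0.0428). In the same 10 Mb it was 1.43 with DESeq2 (Fisher's exact test, p = 8.67e-03), 1.39 with DESeq2 and the replicate block (p = 0.0136), 1.33 with no filter (p = 0.0300) and 1.37 with the GC and length offset (p = 0.0496).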

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

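The thinning of WT replicate 2, the GC and length offset, the test near Cnr2 on genes changed at least 2-fold, the overlap and nearness tests under other fits, and the ribosomal protein share without each library, which kept its direction, were chosen after seeing the data. The count of called genes stayed within 1.5 times of 8053 under each alternative fit, from 7048 (stricter filter) to 8335 (no filter), and was 1988 when a 2-fold change was also required. Without a library it ranged from 7520 to 7811, and the 1988 genes changed at least 2-fold became 1232 with the stricter filter, which tests 9500 genes. Of the 8053 calls, 8003 were shared with the fit with the replicate block, which called 8174, and 7308 with the fit without WT replicate 2, all in the same direction. The labels give no pairing by replicate number. Deviations of same-numbered libraries correlated at 0.141, 0.0494 and 0.112, against -0.129 to 0.0141 for the other pairs. Every library correlated best with its own number, a hint of pairing from the data and not from the design. Cnr2 kept its direction and its call in all alternatives, with log2 fold changes of 0.92 to 1.06 and a highest adjusted p of 1.59e-04. Of 1702 values of 114 named genes under alternatives, 1685 kept direction and side of the threshold, 14 lost the call, 3 gained it and 0 reversed. These involved Acta2, Cd36, Gzma, Id2, Col1a1 and Il5, whose log2 fold change was 0.18 (adjusted p = 9.50e-03) with the GC and length offset. Of the 8 lists passing camera, 1 passed with an estimated correlation. For most lists that lost the call the estimate was above the preset 0.01, such as cytokines (0.109) and glycolysis (0.0982). For chemokine receptors and adhesion it was not (-0.00171). Correlation between members and the construction of the test were therefore not told apart. Fry, which asks only whether a list's genes move on balance in 1 direction, passed 23, and for fry the cause was the construction of the test. The overlap test gave 7 enriched lists, 13 with no filter and 11 with DESeq2, and the cause was not tested. The odds ratio near Cnr2 (Fisher's exact test), 1.21, was 1.33 with no filter (p = 0.0300), 1.43 with DESeq2 (p = 8.67e-03), 1.39 with DESeq2 and the replicate block (p = 0.0136), 1.37 with the GC and length offset (p = 0.0496) and 1.30 in the 20 Mb window (p = 0.0203), 1.21 to 1.36 without a library (p = 0.0428 without WT replicate 2), and 0.999 with the stricter filter; the cause was not tested. With the replicate block, limma-voom and thinning of WT replicate 2 the odds ratio near Cnr2 was 1.18, 1.155 and 1.235, with no p under 0.05. Low counts kept 4438 of the 16588 genes out of the test.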

Other observations

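The 8 gene groups in the next paragraph, and the tests of overlapping genes, library labels, targeted transcript, other cell types, RNA content and flanking DNA, were chosen after the results were seen, as were the DESeq2, limma-voom and unadjusted counts of other splits. The tests on pairs of neighbouring genes were set after stretches with many changed genes had been seen along the chromosomes, and before the pairs were counted.

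Genes of ribosome biogenesis were lower in the libraries labelled Cnr2 KO without exception among those tested. All 38 were lower, with a median log2 fold change of -1.13 (camera adjusted p = 5.98e-36, and adjusted p = 0.0142 with an estimated correlation). Because the groups were picked from these same data, this and the following camera p-values, adjusted over the 8 groups alone, are descriptive and give no independent support. Npm1, a nucleolar chaperone, was at 1646.5 ± 41.7 CPM in WT and 418.6 ± 50.7 CPM in the libraries labelled Cnr2 KO, Ncl was 2.55-fold and Polr1b, an RNA polymerase I subunit, 2.96-fold lower, and Myc, which drives ribosome production, 3.54-fold lower. All 39 listed ribosomal protein genes were lower, with a median of -0.59 (adjusted p = 3.72e-10, and adjusted p = 0.207 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases 17 were lower and 1 higher (adjusted p = 8.14e-04, and 0.193 as adjusted p with an estimated correlation), and of 24 amino acid and polyamine genes 17 were lower and 3 higher (adjusted p = 3.89e-05, and adjusted p = 0.0521 with an estimated correlation), with Odc1, which makes putrescine, 2.82-fold lower. In the other direction, 25 of 27 actin cytoskeleton genes were higher and 0 lower (median 0.58, adjusted p = 3.97e-11, and adjusted p = 0.0315 with an estimated correlation). Cap1, an actin-binding protein, was at 116.2 ± 7.44 CPM in WT and 1343.6 ± 47.6 CPM in the libraries labelled Cnr2 KO. Of 15 interferon-induced GTPases 12 were higher and 3 lower (median 2.08, adjusted p = 1.78e-08, and adjusted p = 0.0142 with an estimated correlation), and Gbp8 was 10.2-fold higher, while Ifitm1, Ifitm2 and Ifitm3, also interferon-induced, were 8.4-fold, 4.0-fold and 6.25-fold lower. Lysosomal genes were 21 higher and 5 lower of 30 (adjusted p = 2.71e-03, and adjusted p = 0.0521 with an estimated correlation), and class I antigen presentation genes 12 higher and 4 lower of 16 (adjusted p = 4.84e-03, and adjusted p = 0.0521 with an estimated correlation).

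The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The labelled split called 8053 genes in edgeR and 1988 at least 2-fold, and was the 1 split of the 10 with as many, against 0 in each of the 9 other splits, where edgeR gave up to 86 genes at an unadjusted p under 0.05 and DESeq2 called up to 2. Limma-voom with quality weights called 8171 genes in the labelled split and up to 7408 in the others. Camera passed 8 lists in the labelled split and up to 10 in the others, and 5 of the 10 splits had at least as many. Each of the 9 other splits sets an uneven mix of both labels against another, so it keeps part of the difference between the labels. These splits therefore do not show what would be called without such a difference, and no conclusion is drawn from their counts.

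Cnr2 was 2.01-fold higher in the libraries labelled Cnr2 KO, against the direction of the label. Scaling, depth and the counting model are argued against by the lowest log2 fold change over the alternatives, 0.92, and reads of an overlapping gene by the 0 annotated genes that overlap Cnr2 on either strand. A single mislabelled library is argued against by the 0 of 6 libraries that correlate best with a library of the other label. A transcript of a targeted allele may still be counted, and this stays open, as does an exchange of all labels between the groups: the table has 1 value per gene and library, and counts per exon would be needed. No biological explanation was tested, since the genotype is itself the label in question.

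Most NF-kB, cytokine and glycolysis genes were lower and most ILC2 genes higher in the libraries labelled Cnr2 KO. The depth of WT replicate 2 is argued against, since 7 of the 8 lists passed in the same direction without it, and GC content or length bias, since the NF-kB median after that offset was -1.05. Macrophages, neutrophils, T, B and red blood cells are argued against as the source of the whole pattern by Lyz2, S100a9, Trac, Igkc and Hbb-bt. The highest value of these genes in any library was 1.78 CPM before TMM scaling. On that scale, however, Trbc2 was at 39.8 CPM in WT and 67.7 CPM in the libraries labelled Cnr2 KO, and Trbc1 at 13.8 and 26.0. Cd3g was at 4.63 and 17.3, Ighm at 3.31 and 28.0, Cd79b at 16.7 and 25.6 and Hba-a1 at 0.829 and 5.13 CPM. Dendritic cells as the source of the whole pattern are argued against by Cd74, H2-Ab1, H2-Aa, H2-Eb1 and Fscn1, of which the highest value was 36.7 CPM. Other genes of the dendritic list differed between WT and the libraries labelled Cnr2 KO, with Ccr7 at 464.4 and 7.74 CPM and Xcr1 at 10.2 and 23.4 CPM. A lower RNA content or total output in 1 group that moves all genes alike cancels in the gap between the ILC2 and NF-kB medians. That gap was at least 1.88 on the log2 scale in every fit. Such a shift alone could not set the 2 lists apart, but the gap cannot show whether output differed between the groups. Absolute amounts, which need spike-ins, stay open. Cells of further types, the genotype named by the labels, or a difference in activation or culture between groups could underlie the pattern and were not tested.

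Neighbouring genes tended to change together. Among 6569 pairs of adjacent tested coding genes at least 10 kb apart, 161 had both members changed at least 2-fold in the same direction, against a mean of 90.3 and a 95th percentile of 106 in 1000 shuffles within expression bins (permutation p = 0.001, the smallest they can give). The excess was therefore not confined to genes closer than 10 kb. Transcription running on past 10 kb into the next gene stays open, since strand was not used in choosing the pairs. Among pairs with different first 3 letters in their symbols there were 132, against a mean of 83.6 and a 95th percentile of 98, which argues against reads shared within families that share those letters. Most of the 161 pairs lie on chromosomes other than chromosome 4, which flanking DNA of another strain around Cnr2 would not reach. For pairs near Cnr2 that explanation stays open. The odds ratio for genes changed at least 2-fold within 10 Mb was 1.21 (Fisher's exact test, p = 0.287, 95% interval 0.827 to 1.74), which leaves room for some enrichment. Over all called genes it was 1.43 with DESeq2 (Fisher's exact test, p = 8.67e-03) and 0.999 with the stricter filter. Shared regulation of neighbouring genes is a candidate explanation for pairs such as Il10 and Mapkapk2 (log2 fold changes of -3.31 and -1.15), chosen after their values were seen, and was not tested.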
